A study of Mus musculus with 4 samples.

How the data were processed

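Colon RNA of 4 groups of mice was measured on 1-colour arrays: mock, TNBS, TNBS with ginger extract and TNBS with zingerone, 1 array each. Per the labels, 5 µg of total RNA was amplified and labelled with Cy3. The deposited table holds 1 Cy3 intensity per probe and array on a linear scale. The submitters' processing notes name limma without a version or a role; scanner settings, background handling and normalization are not given in the sources used here. The values themselves show what was done. The sorted deposited intensity values differ by at most 1.84% between arrays, as after quantile normalization. The lowest deposited intensity is 74.2 and the lower quartile of the mock array is 165, so background does not seem to have been subtracted, and folds of dim probes are understated. Values end at 64634, near the limit of a 16-bit scanner. Since the arrays share 1 distribution, a level near the top is mainly a rank.

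Probe names came from the platform annotation: 21020 of 29922 probes have 1 gene symbol, none has several and 8902 have none. Symbols were updated through the synonyms of the RefSeq gene table of assembly GRCm38.p6: 17558 were current, 3410 were updated and 52 kept the annotation's name. No genome build is given for the values, so no coordinates are printed. Intensities were taken to log2 with no pseudocount, and different probes of 1 gene were averaged. A gene was kept as measured if it reached the median of the named probes on at least 1 of the 4 arrays, which left 10056 of 16637 genes, 7915 of them with 1 probe and 2141 with several. Probes of 1 gene often disagreed: over 1119 genes with 2 probes the median gap between the probes' TNBS-minus-mock differences was 0.41 (log2) and the 95th percentile 1.31, and where the first probe passed 2-fold, the second did so the same way for 16 of 93 genes and had the same sign for 75. Against TNBS, the second probe passed 2-fold the same way for 4 of 28 genes on ginger and 8 of 75 on zingerone. Against mock these were 1 of 16 and 0 of 15, and between ginger and zingerone 0 of 9.

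With 1 array per group there are no residual degrees of freedom and no test was run. Each of the 6 comparisons gives the log2 difference of 2 arrays and the number of genes at least 2-fold apart. The 36 gene lists were fixed before the data were examined. For each, the median log2 difference was set among 10000 random lists of the same size, drawn from measured genes of similar mean expression (10 bins), and called above or below outside the central 95%. This describes these arrays and is no test of the treatments. The lists were IL-1 signalling, NF-κB and I-κB proteins and kinases, inflammatory cytokines and effectors, chemokines, and markers of neutrophils, monocytes and macrophages, T and NK cells, B and plasma cells, mast cells, eosinophils, absorptive colonocytes, goblet cells, enteroendocrine cells, crypt base and stem cells, endothelium, enteric neurons and glia, and adipocytes. They also covered genes of cell division, smooth muscle, fibroblasts and matrix, matrix proteases and inhibitors, skeletal muscle, exocrine pancreas, small intestine, red blood cells, interferon response, MHC class II presentation, antimicrobial and mucosal defence, NRF2 targets, xenobiotic metabolism, fatty acid oxidation and ketogenesis, unfolded protein response, hypoxia and glycolysis, immediate early and handling stress, tight junctions, and reference genes.

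Genes named in the text follow a rule fixed in advance. It takes the 10 largest increases and decreases of TNBS against mock and of ginger and zingerone against TNBS, 5 each between ginger and zingerone, the 2 members with the largest difference of each list outside the central 95%, and 18 further genes always. Symbols that describe no gene were skipped, as were olfactory and vomeronasal receptors. Muc2, Cntn4 and Nr1d2 have probes whose TNBS-minus-mock differences differ in sign and are given with the values of single probes. Genes named outside it were chosen after their values were seen: Il18, Casp1, Igtp and Car1 in the comparisons, and those of the closing part on other observations.

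Alternative settings chosen in advance were quantile normalization, equal array medians, a floor at the 25th percentile, no filter on dim genes, a filter at the 75th percentile, the brightest probe per gene, and random lists from all measured genes. Subtraction of each array's 5th percentile, with values under 50 raised to 50, and removal of probes that stand apart on 1 array were added after seeing the data. A probe stands apart if it is at least 4-fold from the nearest of the other 3 arrays, which lie within 1.41-fold of each other. Shares carry exact (Clopper-Pearson) 95% intervals.

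The steps were checked on simulated data for TNBS against mock with 9915 genes, with noise taken from the ginger-minus-zingerone difference. Without replicates the error of TNBS against mock is unknown, so the simulated rates check the steps and are no error rates of that comparison. Of genes changed by a true 2-fold, 38 of 68 passed the 2-fold threshold the right way, as did 50 of 50 at 4-fold and 71 of 71 at 8-fold, while 73 of 9726 unchanged genes passed it. Of 200 random lists 14 fell outside the central 95%, and all 50 lists shifted by 0.5 (log2) were called. Probes without a gene name (3135 of them measured) were left out of the comparisons. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.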

Results

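Gene expression was measured in the colon of female mice, with the strain labelled BALC/c, on 1-colour arrays hybridised with Cy3-labelled amplified RNA. A total of 24 mice formed 4 groups of 6. Vehicle alone, a volume of 0.1 ml with 50% ethanol, was given to mock mice. The TNBS group received 250 mg/kg trinitrobenzene sulfonic acid, a hapten used with ethanol to provoke colitis in rodents, in the same vehicle. Another group received TNBS mixed with ginger extract, and the last received TNBS mixed with zingerone, a phenolic ketone found in ginger. Tissue was taken on day 7. There was 1 array per group and therefore no replicate, so no difference has an error or a p-value, and the number of arrays limits the precision. The labels do not say whether an array held RNA of 1 mouse or of a pool, nor which amounts of ginger or zingerone its mice received. Each array held 29922 probes, with a median intensity of 238.2 on the mock array and 238 on the ginger array. Of 16637 named genes, 10056 reached the median of the named probes (270.5 on mock) on at least 1 array and are called measured. A gene is called higher or lower where 2 arrays differed at least 2-fold.

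The TNBS and mock arrays show the colitis model itself. Chemokines that attract neutrophils stood among the largest increases: Cxcl3 had an intensity of 167.5 on the mock array and 37402 on the TNBS array, 223-fold higher, and Cxcl2, Cxcl1 and Cxcl5 were 80.2-fold, 54.0-fold and 44.5-fold higher. Ccl4, a monocyte chemoattractant, was 53.6-fold higher. The neutrophil proteins S100a9 and S100a8 were 57.0-fold and 34.9-fold higher, and the siderophore-binding protein Lcn2 was 109-fold higher. Wfdc21 (70.0-fold) and Ifitm6 (45.4-fold) also ranked among the 10 largest increases. The deepest decreases included the pentraxin Mptx1 (22.7-fold lower), the epithelial immunoglobulin transporter Pigr (9.85-fold), Gsdmc4 (9.85-fold), the carbonic anhydrase Car4 (8.04-fold), Medag (8.16-fold) and Smim6 (7.56-fold). In all, 511 genes were higher and 455 lower on the TNBS array.

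The series title names interleukin-1β signalling and NF-κB activity. Il1b, which encodes that cytokine, was at 719 on the mock array and 14298 on the TNBS array, 19.9-fold higher. Its decoy receptor Il1r2 was 27.2-fold higher, Irak3 6.43-fold, the receptor Il1r1 5.02-fold, the antagonist Il1rn 3.69-fold and Il1a 2.38-fold. The Il1a value is the mean of 2 unlike probes, higher by 2.12 and by 0.38 on the log2 scale. Among the 16 measured IL-1 signalling genes 7 were higher, and 2 were lower: Il18 by 2.48 and Casp1 by 1.46 on the log2 scale, both named after their values were seen. The list's median of 0.26 (log2, TNBS minus mock) lay above the central 95% of random lists, at percentile 97.9, but at 92.3 with dim genes kept, where the median was 0.10, and just inside the range with the brightest probe per gene. Of 15 measured NF-κB and I-κB proteins and kinases, 6 were higher and none lower, with a median of 0.53. Regulators that NF-κB itself induces led this list: Tnfaip3 was 6.14-fold higher, Nfkbiz 5.48-fold and the inhibitor Nfkbia 5.30-fold. The subunit genes Nfkb1 (370 on mock, 361.8 on TNBS) and Rela (1020 and 1073.5) differed by less than 2-fold. The arrays give transcript levels only, and NF-κB activity itself was not measured.

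Further lists, inflammatory and other, were also high on the TNBS array. Of 12 measured neutrophil markers 9 were higher, including the collagenase Mmp8 (27.5-fold) and Retnlg (18.6-fold), with a list median of 2.73. Among 22 chemokines 11 were higher (median 0.998; Ccl2 8.55-fold), and among 11 inflammatory cytokines and effectors 7 were higher (median 1.21). Csf3 was 8.62-fold higher, Il6 7.85-fold, Il11 4.29-fold and Ptgs2 3.73-fold, while Tnf differed 1.69-fold. Nos2 did not reach the median of the named probes on any array. Immediate early and handling stress genes, called immediate early genes below, had 7 of 14 members higher (median 0.995). Dusp1 was at 24.8-fold, Ier3 at 11.5-fold and Nr4a1 at 8.49-fold. Matrix proteases and inhibitors had 5 of 14 higher (median 0.73), with Timp1 at 36.2-fold, Plaur at 21.2-fold and Plat at 8.05-fold. Of 15 fibroblast and matrix genes, 6 were higher (median 0.93; Vim 5.61-fold, Col4a1 4.39-fold). Hypoxia and glycolysis genes had 4 of 14 higher (median 0.75; Pfkfb3 from 820.5 to 3278, Vegfa 3.84-fold). Adipocyte markers had 4 of 11 higher (median 0.41), among them Fabp4 (4160 on mock, 45906 on TNBS) and Cfd (3.69-fold). The lists of NRF2 targets (median 0.30; Hmox1 4.46-fold, Gsr 2.67-fold), endothelial markers (0.49; Lyve1 2.79-fold, Eng 2.16-fold) and unfolded protein response genes (0.36; Ddit3 1.90-fold and Atf3 1.73-fold, with no member 2-fold higher) lay above random lists as well.

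The goblet cell, absorptive colonocyte, interferon-stimulated and small intestine lists were low on the TNBS array. Among 16 goblet cell markers 7 were lower and none higher (median -0.83), with Spink4 4.78-fold lower, Creb3l4 3.70-fold, Retnlb 2.87-fold and the transcription factor Atoh1 2.85-fold. The mucin gene Muc2 is uncertain, since its 4 probes differed in sign, the brightest being lower by -1.49 and the mean by -0.40. The brightest probe read 9640 on mock, 3420 on TNBS, 9445.5 on ginger and 6773 on zingerone. The other Muc2 probes were dim, at 389.75 or less on every array, and the 1 that was higher on TNBS (by 0.44) was among them. Of 25 absorptive colonocyte markers 7 were lower (median -0.64), including Guca2a, which encodes guanylin (7.45-fold), the chloride-bicarbonate exchanger Slc26a3 (5.69-fold), Fabp2 (4.48-fold) and Lypd8 (3.05-fold), and Emp1 was 7.58-fold higher. Of 21 interferon-stimulated genes 3 were lower, Ifit3 (2.77-fold), Ifi44 (2.75-fold) and Igtp (-1.11 on the log2 scale), with 17 below the mock value and a median of -0.56. Small intestine genes (median -0.38) had 1 of 8 lower, Slc5a1, which was less than 2-fold lower with a floor at the 25th percentile.

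The other 19 lists lay inside the central 95% of random lists. Their medians were 0.16 for monocyte and macrophage markers (3 of 12 higher, with Cd14 at 21.2-fold and Fcgr3 at 6.88-fold), -0.11 for T and NK cell markers, -0.34 for B and plasma cell markers (3 of 11 lower, with Jchain 2.74-fold and Mzb1 2.63-fold), 0.0023 for mast cell markers and -0.0016 for the 2 measured eosinophil markers. Medians were -0.01 for enteroendocrine, -0.10 for crypt base and stem, 0.33 for enteric neuron and glia, and 0.06 for skeletal muscle markers. They were -0.16 for cell division, -0.30 for smooth muscle, -0.40 for exocrine pancreas and 0.46 for red blood cell genes. MHC class II presentation had a median of -0.54, antimicrobial and mucosal defence genes -0.08 (4 of 11 higher, 3 lower), xenobiotic metabolism -0.19, fatty acid oxidation and ketogenesis -0.16, tight junction genes -0.24 and reference genes -0.05. Of 36 lists of unrelated genes 1.8 would lie outside the range, and 17 of the fixed lists did. Genes of 1 fixed list are related and not independent, so more lists can lie outside without any effect of TNBS.

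Probes that are bright on 1 array alone need care. Gngt1 (7524 on TNBS, at most 141.5 elsewhere) and 1 of the 2 Cntn4 probes (26479 on TNBS, 213 for the other probe) reached the top genes in this way, as did Slc26a1, Pomgnt1 and Ccdc122 on the mock array, which were 40.1-fold, 11.3-fold and 8.45-fold brighter there than on TNBS. The probes of Nfkbia and Slfn4 also stood apart on the TNBS array. Clptm1l was bright on the mock and zingerone arrays (21510 and 23980) and dim on the others (1916 and 1860). Deposited intensities seem to carry a background or an added offset, which would pull small values together. With the 5th percentile of each array subtracted, 891 genes were higher and 850 lower. The small intestine list lost its place outside the random range in 3 of 9 alternative settings, the unfolded protein response list in 2 and the endothelial list in 1. Lists inside the range that left it were B and plasma cell markers (in 3 settings), monocyte and macrophage markers and exocrine pancreas genes (in 2 each), and enteric neuron, MHC class II and xenobiotic metabolism lists (in 1 each).

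**Figure D1:**
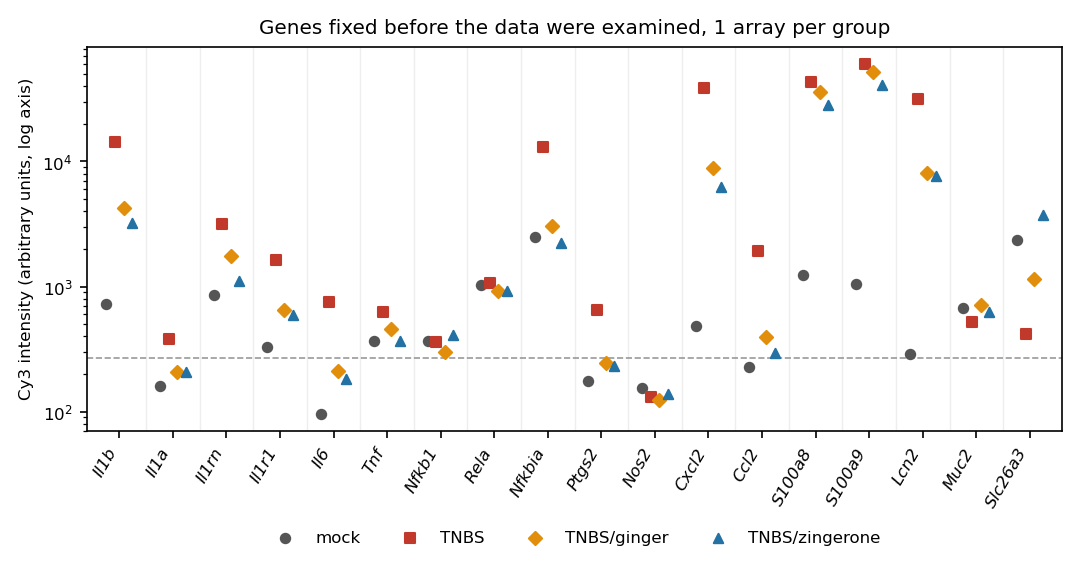
Cy3 intensity (log axis) of 18 genes fixed before the data were examined, with 1 point per array for the mock, TNBS, TNBS/ginger and TNBS/zingerone groups; the dashed line marks the mock median of named probes (270.5). Il1b stood at 719 on the mock array, 14298 on TNBS, 4222 on ginger and 3196 on zingerone, whereas S100a9 stayed at 51922 and 41248 on the ginger and zingerone arrays.

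Ginger extract given with TNBS was compared with TNBS alone to see which of these differences were smaller. On the ginger array 136 genes were higher and 249 lower than on the TNBS array. Gngt1, Cntn4 and Sema4b aside, the largest decreases were in inflammatory genes: Mmp8 was 11.5-fold lower, Ifitm6 9.53-fold, the acute phase gene Saa3 7.69-fold, Cxcl1 7.54-fold, Cxcl5 7.45-fold, Slfn4 7.09-fold and Il1r2 6.92-fold. Il1b was 3.39-fold lower, Lcn2 3.87-fold, Cxcl2 4.44-fold, Ccl2 4.93-fold, Il6 3.56-fold and Ptgs2 2.68-fold. Among the increases were the epithelial genes Gsdmc4 (5.80-fold) and Guca2a (5.34-fold). S100a8 (1.19-fold lower) and S100a9 (1.15-fold lower) differed little, but both lay near the top of the intensity scale, which ended at 64634 on every array.

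By list, neutrophil markers had 6 of 12 members lower (median -1.07; Retnlg 5.68-fold), chemokines 9 of 22 (median -0.89), immediate early genes 5 of 14 (-0.80; Dusp1 5.97-fold) and cytokines and effectors 4 of 11 (-0.73; Csf3 4.97-fold). IL-1 signalling genes had 4 of 16 lower and 1 higher (-0.36), and NF-κB and I-κB proteins and kinases 4 of 15 lower (-0.33), with Nfkbia 4.34-fold, Tnfaip3 3.92-fold and Nfkbiz 3.81-fold lower. Nfkb1 (302.2 on ginger) and Rela (927.2) stayed within 2-fold of the TNBS array. Fibroblast and matrix genes (-0.50; Vim 2.95-fold, Col4a1 2.75-fold), matrix proteases and inhibitors (-0.45; Plat 5.03-fold, Timp1 4.60-fold) and adipocyte markers (-0.47; Fabp4 4.60-fold, Cfd 3.36-fold) each had 4 members lower. Monocyte and macrophage markers (-0.22; Cd14 6.65-fold, Fcgr3 3.19-fold) and endothelial markers (-0.22; Lyve1 2.27-fold) lay below random lists. So did interferon-stimulated genes (-0.35; Isg15 2.24-fold and Rsad2 1.97-fold lower), a list that was already low on the TNBS array.

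Lists above the random range were goblet cell markers (4 of 16 higher, median 0.76; Spink4 3.30-fold, Atoh1 2.70-fold), absorptive colonocyte markers (4 of 25 higher, 1 lower, 0.44; Fabp2 3.24-fold, Slc26a3 2.74-fold) and cell division genes (0.47), of which 16 of 17 lay above the TNBS value but Mcm5 alone by 2-fold (2.39-fold). Fatty acid oxidation and ketogenesis (0.41; Acaa2 2.29-fold, Ech1 1.66-fold), xenobiotic metabolism (0.30; Ces2a 2.02-fold, Nr1i2 1.86-fold) and B and plasma cell markers (0.27; Jchain 1.64-fold, Mzb1 1.61-fold) were higher as lists with at most 1 member past 2-fold. The 2 eosinophil markers (0.83) rested on Epx (2.92-fold), with Prg2 at 1.09-fold. The remaining 17 lists, smooth muscle (-0.02) and reference genes (0.26) among them, lay inside.

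Most of the other top increases on the ginger array came from 1 probe that was bright there alone: Mesp1 (5979 against at most 134 on the other arrays), Hsd17b14 (2208), Opn1sw (1936), Natd1 (1298), Gng8 (2373), Wfikkn2 (915) and Folr2 (1264). Hsh2d, at 4736 on ginger and 893 on TNBS, was the other one. Sema4b was dim on both the ginger (156.2) and zingerone (98.25) arrays and at 1458 on TNBS. After background subtraction 329 genes were higher and 430 lower. The IL-1 list median was -0.078, at percentile 5.96, with dim genes kept, and the lists of B and plasma cell, eosinophil and endothelial markers and of xenobiotic metabolism lost their place in 1 to 3 alternative settings, while tight junction genes left the range in 4, enteric neuron markers and MHC class II genes in 2 each and exocrine pancreas genes in 1.

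Zingerone given with TNBS was compared with TNBS alone in the same way, and 460 genes were higher and 298 lower. Gngt1, Cntn4, Sema4b and Tmem258 aside, inflammatory genes again led the decreases: Cxcl1 was 21.2-fold lower, Mmp8 13.0-fold, Cxcl5 12.0-fold, Cxcl3 9.84-fold and Retnlg 8.77-fold, and Ifitm6 fell by 3.46 on the log2 scale. Il1b was 4.47-fold lower, Il1r2 7.73-fold, Il1rn 2.86-fold, Ccl2 6.53-fold, Cxcl2 6.21-fold, Il6 4.12-fold and Lcn2 4.10-fold, while S100a8 (1.51-fold) and S100a9 (1.45-fold) stayed high. Guca2a was 12.5-fold higher and Slc26a3 8.86-fold, and both exceeded the mock value (34596 against 20660, and 3704 against 2377). Smim6 (8.06-fold), Mettl7b (6.21-fold) and the matrix protein Thbs4 (5.55-fold) were also among the largest increases.

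Of 25 absorptive colonocyte markers 9 were higher and 1 lower (median 0.69), and of 16 goblet cell markers 4 were higher (0.73; Spink4 3.43-fold, Retnlb 2.55-fold). Cell division genes (0.55; Mcm5 2.14-fold, Plk1 2.11-fold), xenobiotic metabolism genes (0.60; Ces2a 2.33-fold) and small intestine genes (0.65; Alpi, intestinal alkaline phosphatase, 3.25-fold) lay above random lists. Below them were neutrophil markers (6 of 12 lower, -0.92), immediate early genes (5 of 14, -0.80; Dusp1 7.55-fold), cytokines and effectors (5 of 11, -0.79; Il11 4.48-fold) and chemokines (8 of 22, -0.68). IL-1 signalling genes had 6 of 16 lower and 1 higher (-0.44), and NF-κB and I-κB proteins and kinases 4 of 15 lower (-0.54; Nfkbia 5.83-fold, Nfkbiz 5.12-fold), with Nfkb1 at 413 and Rela at 913.1. Matrix proteases (-0.52; Timp1 7.69-fold), fibroblast and matrix genes (-0.50; Vim 3.70-fold), interferon-stimulated genes (-0.46; Gbp2 1.92-fold and Ifit1 1.77-fold lower, with no member 2-fold apart) and adipocyte markers (-0.40; Cfd 2.35-fold, Fabp4 2.31-fold) were low. Smooth muscle genes (-0.48; Des 2.13-fold, Actg2 2.09-fold), enteric neuron and glia markers (-0.33; Vip 2.11-fold, Sox10 1.43-fold) and the 2 red blood cell genes (-0.68; Alas2 1.74-fold, Slc4a1 1.49-fold) were low as well. The remaining 18 lists lay inside, including reference genes (0.29).

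Dcaf17 (5716 on zingerone, at most 160.5 elsewhere) and Med13l (906.5) were bright on the zingerone array alone, Mex3d was at 2105 there and at 363.2 on TNBS, and Tmem258 (121.2) was dim there alone. Nr1d2 was 7.66-fold higher in the mean of 2 probes, of which 1 read 37402 on zingerone and the other 171.8. After background subtraction 954 genes were higher and 577 lower. With dim genes kept the IL-1 list median was -0.15, at percentile 4.28. The adipocyte, red blood cell, small intestine and enteric neuron lists lost their place in 2, 3, 1 and 4 of 9 alternative settings, while monocyte and macrophage markers left the range in 3, fatty acid oxidation genes in 2, and endothelial markers and tight junction genes in 1 each.

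**Figure D2:**
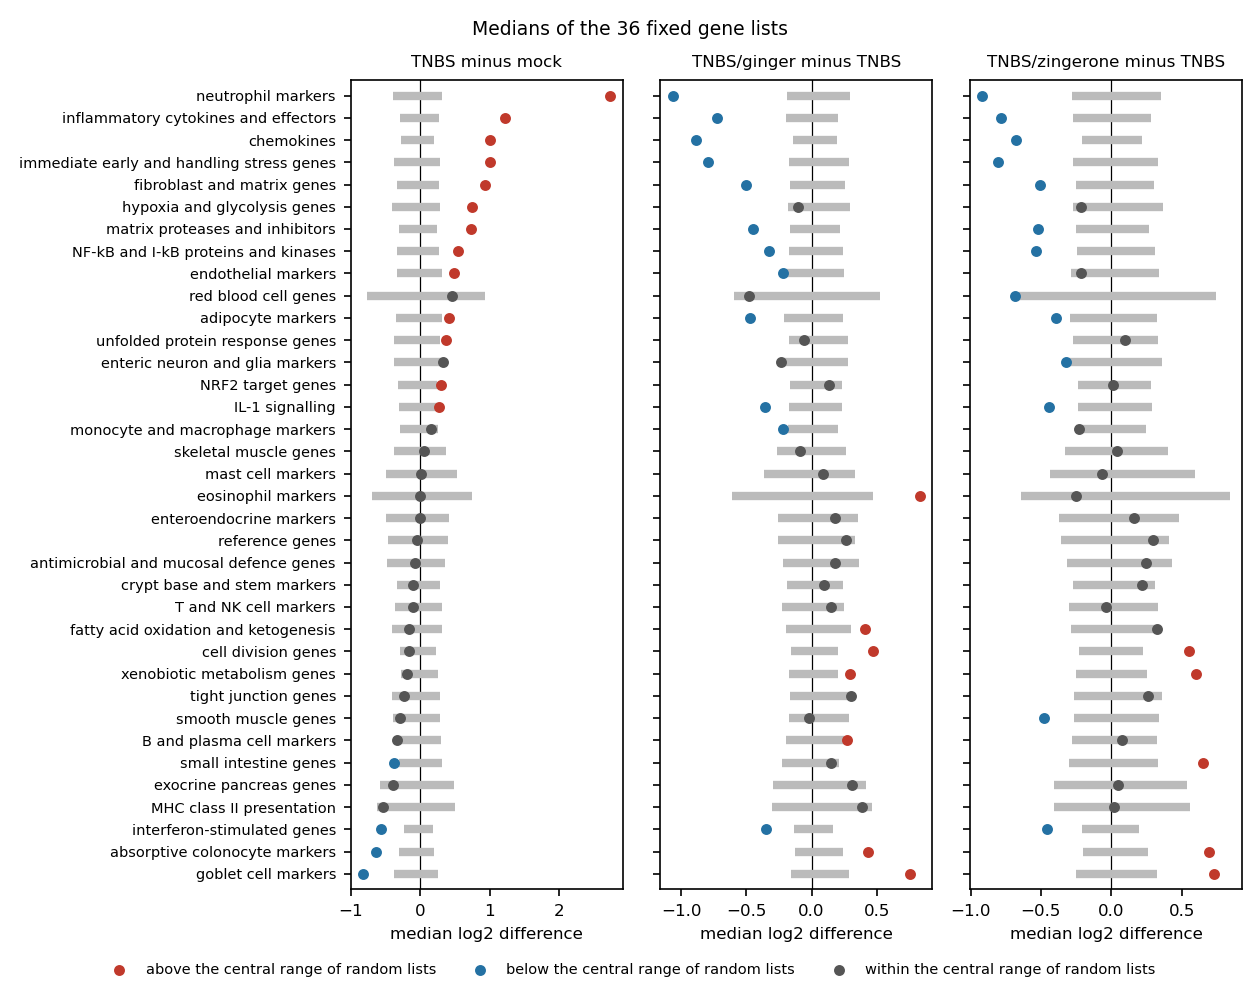
Median log2 difference of each of the 36 fixed lists (points) in 3 comparisons, with the central 95% of 10000 random lists of the same size and expression as grey bars; point colours mark medians above, below or within that range. Neutrophil markers moved from 2.73 above mock to -1.07 and -0.92 relative to TNBS, and goblet cell markers from -0.83 to 0.76 and 0.73.

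The ginger and zingerone arrays were closer to each other than either was to the TNBS array, with 36 genes higher on ginger and 75 higher on zingerone. Absorptive colonocyte genes were higher on zingerone: 4 of 25 by at least 2-fold and none the other way (list median -0.14, ginger minus zingerone), namely Slc26a3 (3.23-fold), Lypd8 (2.88-fold), Guca2a (2.34-fold) and Car1 (by 1.03 on the log2 scale). Cxcl1 was 2.81-fold higher on ginger, but 1 other of the 22 chemokines was at least 2-fold lower and the list median (0.0084) lay inside random lists. Smooth muscle genes were higher on ginger in 14 of 15 cases (median 0.39), with Actg2 2.24-fold and Tpm2 1.77-fold higher. Adipocyte markers were lower on ginger (median -0.42; Fabp4 1.99-fold, Lep 1.74-fold), as were small intestine (-0.28; Apob 1.70-fold, Alpi 1.57-fold) and xenobiotic metabolism genes (-0.22; Mgst1 1.37-fold), although Cyp1a2 was 1.37-fold higher. Above random lists were MHC class II presentation (0.35; H2-DMb2 1.53-fold, H2-Eb1 1.36-fold), T and NK cell markers (0.29; Cd3g 1.76-fold, and Cd3d 1.57-fold lower), enteroendocrine markers (0.25; Sst 1.72-fold, Neurog3 1.38-fold), cytokines and effectors (0.24; Il11 1.84-fold), matrix proteases (0.23; Mmp10 1.96-fold, Mmp3 1.69-fold), hypoxia genes (0.22; Ndrg1 1.46-fold, Adm 1.37-fold), neutrophil markers (0.20), interferon-stimulated genes (0.15) and the 2 eosinophil markers (1.08). IL-1 signalling (0.12) and NF-κB genes (0.13) lay inside the range, but NF-κB genes lay above it with the dim-gene filter at the 75th percentile (0.23). Of the 10 extreme genes, Mesp1, Hsd17b14, Opn1sw and Natd1 (bright on ginger alone), Dcaf17 and Med13l (bright on zingerone alone) and Tmem258 (dim on zingerone alone) come from probes that stand apart on 1 array, and the others were Clptm1l, Mex3d and Nr1d2. No amount of either compound is known for these arrays, so matched doses cannot be claimed. After background subtraction 73 genes were higher on ginger and 324 higher on zingerone, a more uneven split. The lists of cytokines, neutrophil, T and NK cell and enteroendocrine markers and of small intestine, interferon-stimulated and xenobiotic metabolism genes lost their place in 1 to 5 alternative settings, and skeletal muscle genes left the range in 1.

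Against the mock array, 163 genes were higher and 109 lower on ginger, and 154 higher and 106 lower on zingerone. Neutrophil markers lay above random lists on ginger (median 1.05) and zingerone (0.73), as did cytokines and effectors (0.49 and 0.26), hypoxia and glycolysis genes (0.60 and 0.39), fibroblast and matrix genes (0.43 and 0.34), NRF2 targets (0.39 and 0.32), matrix proteases (0.32 and 0.37) and immediate early genes (0.25 and 0.28). Antimicrobial genes (0.34 and 0.36) and cell division genes (0.22 and 0.25), inside the range on TNBS, also lay above on both. Interferon-stimulated genes (-0.67 and -0.75) and MHC class II presentation (-0.41 and -0.76) lay below on both. Enteroendocrine (0.36) and eosinophil (0.83) markers lay above and absorptive colonocyte (-0.16) and small intestine genes (-0.27) below on ginger; chemokines (0.25) lay above and B and plasma cell markers (-0.29) and smooth muscle genes (-0.38) below on zingerone. IL-1 signalling genes lay inside on ginger (0.11) and zingerone (0.0017), and so did NF-κB genes (0.21 and 0.089), but on ginger NF-κB genes lay above in 3 alternative settings and IL-1 genes in 1. After background subtraction the counts were 305 and 288 for ginger and 391 and 203 for zingerone. On zingerone the cytokine list lost its place in 5 of 9 settings, cell division in 3, immediate early genes in 2, and fibroblast and antimicrobial genes in 1 each; on ginger enteroendocrine and antimicrobial genes lost theirs in 2, and eosinophil, colonocyte, cell division, small intestine, MHC class II and immediate early genes in 1 each. Further lists left the range in some settings: on ginger chemokines in 4 and B and plasma cell markers in 1, and on zingerone exocrine pancreas and red blood cell genes in 2 each and T and NK cell, colonocyte and adipocyte markers in 1 each.

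How far the ginger and zingerone arrays lay back towards mock was read from the genes called on TNBS against mock. Of the 511 genes higher on TNBS, the ginger array moved 44.6% back by at least 2-fold (exact 95% binomial interval 40.3 to 49.0) and the zingerone array 50.9% (46.5 to 55.3). Of the 455 lower genes, the ginger array moved 20% back by that much (16.4 to 24.0) and the zingerone array 54.7% (50.0 to 59.4). These intervals treat genes as independent, which they are not. Within 2-fold of mock lay 74.0% of the higher and 81.3% of the lower genes on ginger, and 79.6% and 85.9% on zingerone. The median share of the TNBS-minus-mock difference left on ginger was 40.5% for higher and 49.9% for lower genes, a smaller contrast than that of the 2-fold shares. On zingerone 32.8% and 20.8% were left. Genes picked as extremes on 1 array come back on any other array to some degree. With the roles exchanged, of the 272 genes at least 2-fold from mock on ginger, the TNBS array moved 11.03% back by 2-fold. Of the 966 genes picked on TNBS the ginger array moved 33.0% back. Of the 260 genes picked on zingerone the TNBS array moved 18.1% back, against 52.7% that the zingerone array moved back. Such shares do not tell an effect of the compounds from milder colitis in the sampled mice.

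All comparisons share arrays, which alone makes differences correlate across genes, and genes are not independent replicates. The TNBS-minus-mock and ginger-minus-TNBS differences had r = -0.78 across genes, against -0.50 in 100 simulations of unchanged arrays, with a covariance of -0.25 against -0.06. For zingerone r was -0.76 against -0.50, with a covariance of -0.31 against -0.06. The ginger-minus-TNBS and zingerone-minus-TNBS differences had r = 0.79 against 0.50, with a covariance of 0.21 against 0.06. Both compounds' arrays were lower than TNBS for 214 genes, against 19.2 in the simulations and 7.38 for independent lists, and higher for 91, against 19.3 and 6.22. The simulated arrays all took their noise from the ginger-minus-zingerone difference. A TNBS array with more error of its own would exceed these simulations without any effect. With 1 TNBS array the shared array cannot be split, so part or all of this excess may come from it.

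**Figure D3:**
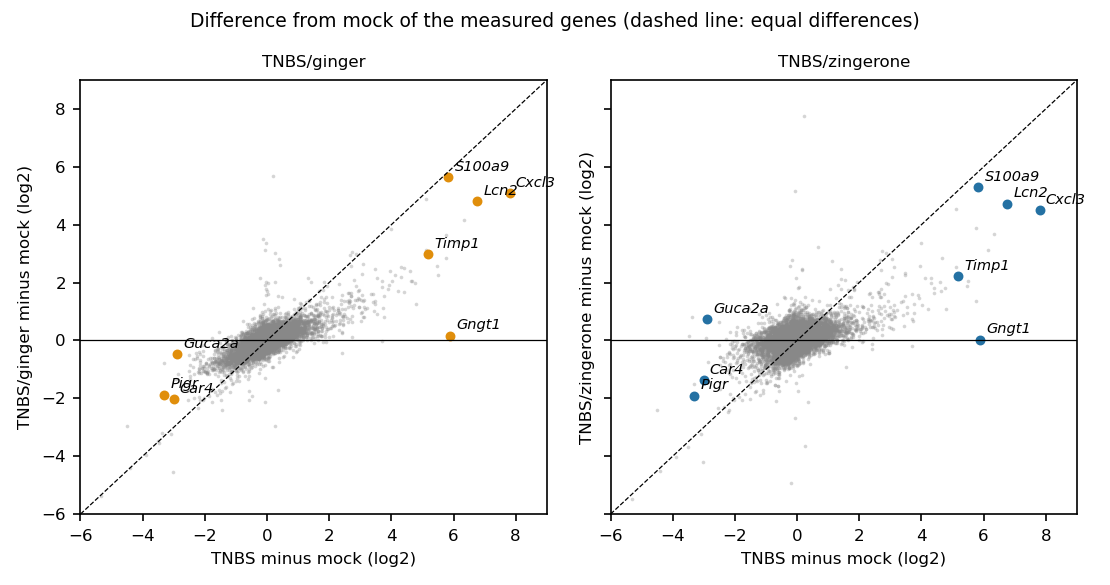
Log2 difference from mock of the 10056 measured genes on the ginger (left) and zingerone (right) arrays against that on the TNBS array, 1 point per gene; the dashed line marks equal differences and the horizontal line no difference from mock. Genes high on TNBS lie mostly below the dashed line, and Guca2a lies above 0 on the zingerone array only.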

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

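The tests of single-spot faults, of a common factor, of severity and of muscle share below were chosen after the result was seen, as were those with exchanged roles on zingerone and by direction; the test with exchanged roles on ginger over both directions was not. With 1 array per group no sample can be compared with others of its group. Signal outside the comparisons came from the 3135 measured probes without a gene name, of which 131 were at least 2-fold higher and 135 lower on TNBS than on mock. Among named genes 5.08% were higher. Probe mMR026724 was higher by 8.91 (log2), reading 49594 on TNBS, 103 on mock, 109 on ginger and 103 on zingerone, and so stood apart on 1 array. Probe mMC022500, lower by -6.10, did so on mock (10029, against 146.2 on TNBS). Probes mMC020473 (by 4.75, from 213.5 to 5744) and mMR030208 (by 4.73, from 1112 to 29551) were also high on TNBS, and read 776.2 and 10554 on ginger and 550.8 and 6066 on zingerone.

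The first pattern is the smaller TNBS response on the ginger and zingerone arrays. Regression of extremes picked on 1 array was tested by exchanging roles. The TNBS array moved 11.03% (7.57 to 15.4) of the genes picked on ginger back by 2-fold, against 33.0% observed. Of those picked on zingerone it moved 18.1% (13.6 to 23.3) back, against 52.7%. Over both directions together this argues against regression of equal size on every array as the whole cause. A TNBS array with more error of its own would give the same asymmetry, which 1 array per group cannot exclude. The intervals also treat genes as independent, which they are not. By direction the exchanged shares on ginger were 13.5% (8.66 to 19.7) of higher and 7.34% (3.22 to 13.95) of lower genes, against 44.6% and 20%. On zingerone they were 22.7% (16.4 to 30.2) and 11.3% (5.99 to 18.9), against 50.9% and 54.7%. The upper bound passed 50% of the observed share, the limit set for the test, for lower genes on ginger and higher genes on zingerone. There regression of equal size stays open as well. A damping of every difference by 1 factor would bring interferon-stimulated genes back up, yet their median was -0.35 on ginger and -0.46 on zingerone relative to TNBS, below random lists on both. Whether the compounds or milder colitis in the sampled mice, by chance or handling, account for the pattern cannot be told apart with 1 array per group.

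The second pattern is the 35 probes bright on 1 array alone, 24 of them below the median of the named probes on the other 3 arrays, such as Mesp1, Gngt1, Slc26a1 and Dcaf17. A fault of a single spot may account for them: in genes with at most 3 probes, 0 of 12 other probes moved 2-fold the same way, which allows up to 26.5%. Among genes with another probe at least 4-fold higher on TNBS the share was 8 of 29 (27.6%, 12.7 to 47.2), so the other probes are too few and too often silent to decide. A biological explanation was not tested, because no group has a second array.

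The third pattern is smooth muscle genes, lower on the zingerone than on the ginger array. A smaller share of muscle layer in that sample would raise the markers of every other cell type alike. Absorptive colonocyte markers exceeded enteroendocrine markers by 0.39 (log2, zingerone minus ginger, bootstrap 95% interval 0.02 to 0.66), a pair compared after both lists had been seen on opposite sides, and goblet cell markers by 0.13 (-0.0054 to 0.36). Enteric neuron and glia markers, which lie partly in the muscle wall, had a median of 0.15 (ginger minus zingerone), inside random lists, with 6 of 7 higher on ginger, and T and NK cell markers had one of 0.29, above random lists. Medians (ginger minus zingerone) of goblet cell (-0.01), endothelial (-0.02) and fibroblast and matrix genes (-0.06) lay inside random lists. Enteroendocrine markers (0.25) lay above, and absorptive colonocyte (-0.14) and adipocyte markers (-0.42) below. Markers of other cell types were thus not all higher on zingerone. With these values in single samples a smaller muscle share stays open, as does an effect of the compounds, which was not tested.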

How the results depend on the processing

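Background subtraction and removal of probes that stand apart on 1 array were added after seeing the data. No result reversed in any of the settings run. Of 96 recomputed counts 84 stayed within 1.5 times, and the other 12 all moved under background subtraction, in which dim genes gain fold by construction. There, the counts of higher and lower genes were 891 and 850 for TNBS against mock, 329 and 430 for ginger and 954 and 577 for zingerone against TNBS, 73 and 324 for ginger against zingerone, and 305 and 288 for ginger and 391 and 203 for zingerone against mock. Genes lower on TNBS then moved back on ginger in 26.2% and on zingerone in 66.6%; the other 30 of 32 shares stayed inside their intervals. IL-1 signalling was no longer outside random lists with dim genes kept, its median being 0.10 for TNBS against mock, -0.078 for ginger and -0.15 for zingerone against TNBS. With the brightest probe per gene it kept its value of 0.26 for TNBS against mock but fell just inside the range. With the filter at the 75th percentile NF-κB genes lay above for ginger against zingerone (0.23), as did IL-1 genes for ginger against mock (0.43). For ginger against mock NF-κB genes (0.21) lay above with quantile normalization, with a floor and with random lists from all measured genes. The cause of these was not tested. Over the lists of all 6 comparisons 1830 of 1938 values kept their side of the range, 64 lost and 44 gained a place outside it. Of 6108 values of named genes 6034 kept their side of 2-fold, 69 passed it, and 5 no longer did (Slc5a1 against mock on TNBS, Lep and Mmp8 on zingerone with a floor, and Il6 on ginger with a floor or background subtraction). Quantile normalization and equal medians move almost nothing in values that already share 1 distribution and so say little about stability. No paired analysis was possible because each group has 1 array. Signal over background limits dim genes most: their folds are understated, and no value lies near 0.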

Other observations

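The gene groups and genes in this part were chosen after their values were seen, the groups by symbol, except the lists named as fixed. Choice by the start of the symbol does not set kinases named Rps6k apart from cytosolic ribosomal proteins. Nor does it set assembly factors named Ndufaf apart from respiratory chain genes. Genes of the mitochondrial respiratory chain and ATP synthase were low on the TNBS array as a body: of 70 measured genes 69 lay below the mock value and 28 at least 2-fold, with a median of -0.70 (log2), against a central range of random lists of -0.27 to 0.09. Atp5b was at 13062 on mock, 3396 on TNBS, 5874 on ginger and 18134 on zingerone. Cox5a was at 17079, 4237, 9252 and 14803, Ndufb3 at 3298, 765.5, 1504 and 3186, and Ndufs1 at 2711, 869.8, 1653 and 2348 in that order. Relative to TNBS the group's median was 0.44 on ginger, with 69 of 70 higher but 2 by 2-fold, and 0.47 on zingerone, with 68 higher and 14 by 2-fold. Relative to mock it stayed at -0.29 and -0.18. For ginger minus zingerone the group's median was -0.13, below random lists (-0.02 to 0.11), with 48 of 70 lower on ginger and 22 higher. Of these, 4 were lower by 2-fold. Markers of goblet cells and absorptive colonocytes, in lists fixed before the data were examined, moved with this group. The median of goblet cell markers was -0.83 on TNBS relative to mock, then 0.76 on ginger and 0.73 on zingerone relative to TNBS. That of absorptive colonocyte markers was -0.64, then 0.44 and 0.69. The fixed lists of enteroendocrine (-0.01) and crypt base and stem markers (-0.10) lay inside random lists on TNBS relative to mock. They did so on ginger and zingerone relative to TNBS too. Mitochondrial ribosomal proteins (67 genes) had a median of -0.21 on TNBS relative to mock, cytosolic ribosomal proteins (23 genes) -0.21 and proteasome subunits (34 genes) -0.10, all inside their ranges. Mitochondrial ribosomal proteins lay only just inside (percentile 2.87, range -0.22 to 0.09), with 51 of 67 below the mock value. Relative to TNBS, mitochondrial ribosomal proteins lay above random lists on ginger (0.20) and zingerone (0.28), proteasome subunits lay below on ginger (-0.083) and inside on zingerone (-0.056), and cytosolic ribosomal proteins lay inside on both (0.12 and 0.13).

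Genes of the antimicrobial list went both ways on TNBS. Lcn2, Saa3, Reg3g (by 2.43 on the log2 scale) and Wfdc2 (by 1.20) were higher, while Pigr, Dmbt1 (by -2.48) and Pla2g2a (by -1.78) were lower, and Pla2g2a on ginger (4099) and zingerone (4905) exceeded mock (3821). Of the measured claudins in the tight junction list Cldn4 alone lay above mock on TNBS, by 1.86, while Cldn8 (by -1.72), Cldn3 (-0.98), Cldn2 (-0.75), Cldn7 (-0.28), Cldn15 (-0.28) and Cldn23 (-0.12) lay below. The clock output gene Dbp was at 2670 on mock, 367.8 on TNBS, 1187 on ginger and 1612 on zingerone, and Nfil3, which represses genes that Dbp activates, at 212, 686, 414 and 490.2. Albumin (Alb) did not follow the TNBS response: it was at 3566 on mock and 3412 on TNBS, but 819 on ginger and 553 on zingerone, and the fibrinogen gene Fgb at 833, 1072, 254.5 and 188.8. Fabp4, an adipocyte and macrophage gene, was at 4160 on mock, 45906 on TNBS, 9969 on ginger and 19855 on zingerone.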
